A study of Homo sapiens with 12 samples.

How the data were processed

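RNA levels were measured by RNA-seq in primary human epidermal keratinocytes, the main cell type of the outer skin layer, after 3 days of differentiation in culture. Cells had received a non-targeting control siRNA, or siRNA against KLF3, KLF4, KLF3 and KLF4 together, CBP (gene CREBBP) or P300 (gene EP300). Each of the 6 groups held 2 libraries, 12 in all, and the groups were taken from the sample labels. Nothing in the labels says that the 2 libraries of a group came from separate cultures or donors, so p-values measure the spread between these libraries, which may be technical.

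The authors deposited a table of RPKM values (reads scaled to gene length and to mapped reads), 1 row per gene name and 1 column per library. The submitters' processing notes name STAR, Partek and the hg19 genome build, with no versions and no roles. Gene coordinates were not used here. The authors also deposited 1 table per knockdown with a signed fold change and a p-value per gene, which per the file headers hold genes past an analysis of variance at a false discovery rate of 0.05 with an average fold above 2. The header sentence of the P300 table speaks of the CBP knockdown, but its folds match the P300 libraries. How RPKM was normalized could affect every value. The 3 abundant small RNA genes RN7SL3, RMRP and RPPH1 took 31.9% to 41.9% of the summed RPKM of a library. RPKM is scaled to gene length, so this is not their share of reads, and how much it moves other genes is not known.

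The table had 16289 rows. A group of 22 rows whose names had been turned into calendar dates was left out, as were Y-linked genes, XIST and TSIX, which are not analysed here. That made 41 rows in all and left 16248 genes. No read counts were used, so the absolute depth per library is unknown and no counting interval is given. Low values of a gene fall on steps of 1 read, and comparing these steps between libraries gave relative depths. Against control replicate 1, control replicate 2 had a relative depth of 1.15 and the 10 knockdown libraries lay between 0.431 and 0.607, from 680 to 870 low genes each. Of these genes, 30.7% to 36.6% fell on the steps, against at most 0.901% on shifted steps. The estimates hold only up to a simple ratio, because the next best ratio scored nearly as well. Genes listed at 0 numbered 47 and 27 in the control libraries and 79 to 149 in the 10 knockdown libraries, the direction that lower depth would give. Such numbers also move where genes change, so whether the knockdown libraries had less depth than the controls is not settled.

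Genes with an RPKM of at least 1 in at least 2 libraries were tested, 12067 in all. Differences were tested with limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), with 1 coefficient per group, all 12 libraries in the fit (6 residual degrees of freedom), an intensity trend in the empirical Bayes step, 2-sided tests and Benjamini-Hochberg adjustment at 0.05. Log2 changes are on this log2(RPKM + 1) scale, which understates the change of low genes, and are given with their standard error (SE). Departure from additivity was the double knockdown minus the KLF3 knockdown minus the KLF4 knockdown plus the control. Gene lists were compared with all other genes by limma's camera with a preset correlation of 0.01, adjusted over the lists of each comparison. Unless stated otherwise, the adjusted p of a list is from that test. Gene groups chosen after seeing the data were instead adjusted together over 54 tests, all comparisons included. Camera with an estimated correlation, and fry, which tests only whether a list's genes move on balance one way, were alternatives.

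Before the data were examined, 19 lists were fixed: early differentiation, late differentiation and cornification, late cornified envelope and small proline-rich families, lipid barrier, desmosome and tight junction, basal layer and hemidesmosome, cell cycle, interferon response, inflammation and antimicrobial defence, stress keratins, epidermal transcription factors, p53 targets, KLF and SP family, acetyltransferases with deacetylases and CTBP, cholesterol synthesis, matrix and wound edge, fibroblast markers, melanocyte markers, and Langerhans and other immune cell markers. No melanocyte marker passed the filter, so 18 lists were tested. The genes named were set by a rule fixed at the same time. For each knockdown these are the 5 largest rises and 5 largest falls past the threshold with both knockdown libraries beyond both control libraries, and up to 3 members per list past the threshold with the smallest adjusted p, or the first member where none passed. For the other comparisons they are the 5 largest rises and falls, for overlaps up to 5 genes per direction, and the 4 target genes always. Some results that this rule names are not reported here. Genes of the LCE, SPRR2, KRT6, S100A7 and histone families share near-identical copies, so their values are uncertain between copies.

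Alternatives fixed beforehand were a pseudocount of 0.1, no filter, a minimum RPKM of 5 in 2 libraries, median-ratio scaling, quantile normalization, only the libraries of the groups compared, the replicate number as a block, empirical Bayes without trend, an added fold minimum of 1.5, and leaving out each library in turn. The fits were tested on simulated values with known changes over 12067 genes. For KLF3 knockdown against control, 98% of genes changed by 0.5 and 100% of those changed by 1 or 2 on the log2 scale were recovered, with 5 false calls. For departure from additivity the shares were 64%, 98% and 100%, with 18 false calls. Only 50, 100 and 50 genes were changed by 0.5, 1 and 2, with noise drawn independently for each gene. The numbers of false calls therefore do not carry over to the counts found here. Overlaps between comparisons that share the control libraries were set beside 20 simulations of unchanged groups. Figures were drawn with matplotlib 3.10.9.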

Results

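The data were 12 RNA-seq libraries of primary human keratinocytes, taken 3 days into differentiation after siRNA knockdown of transcription factors KLF3 and KLF4 or of the histone acetyltransferases CBP and P300. The series title places KLF3 and CBP in epidermal differentiation, and the comparisons ask which genes depend on each factor and which genes depend on several. Each group held 2 libraries (n = 2 for every mean ± SD). Between 10676 and 11244 genes reached 1 RPKM per library, and summed RPKM ran from 374926 to 442116. Across genes, which are not independent replicates, the 2 libraries of a group had Pearson correlations of 0.996 to 0.998 on the log2 scale. The first principal component held 51.1% of the variance between libraries, the second 23.5%.

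KLF3 RNA was 36.8 ± 3.05 RPKM in control cells and 8.47 ± 0.0310 RPKM after KLF3 knockdown, 77.0% lower. It was 84.6% lower in the double knockdown. KLF4 RNA was 81.5 ± 5.75 RPKM in control cells and 33.2 ± 4.68 RPKM after KLF4 knockdown, 59.3% lower, and it was 68.9% lower in the double knockdown. CREBBP was 3.78 ± 0.363 RPKM in control cells and 1.08 ± 0.255 RPKM after CBP knockdown. EP300 was 3.96 ± 0.556 RPKM in control cells and 0.642 ± 0.0798 RPKM after P300 knockdown. Each target fell in its own knockdown past the threshold, with adjusted p from 1.18e-09 to 2.83e-06 in limma. KLF3 and KLF4 also fell in the other knockdowns. KLF3 was 49.8% lower after KLF4 knockdown, 59.1% lower after CBP knockdown and 29.3% lower after P300 knockdown. KLF4 was 33.1% lower after KLF3 knockdown, 69.6% lower after CBP knockdown and 35.5% lower after P300 knockdown. EP300 was 24.3% lower after CBP knockdown (adjusted p = 0.0186), whereas CREBBP did not differ detectably after P300 knockdown (adjusted p = 0.994).

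**Figure D1:**
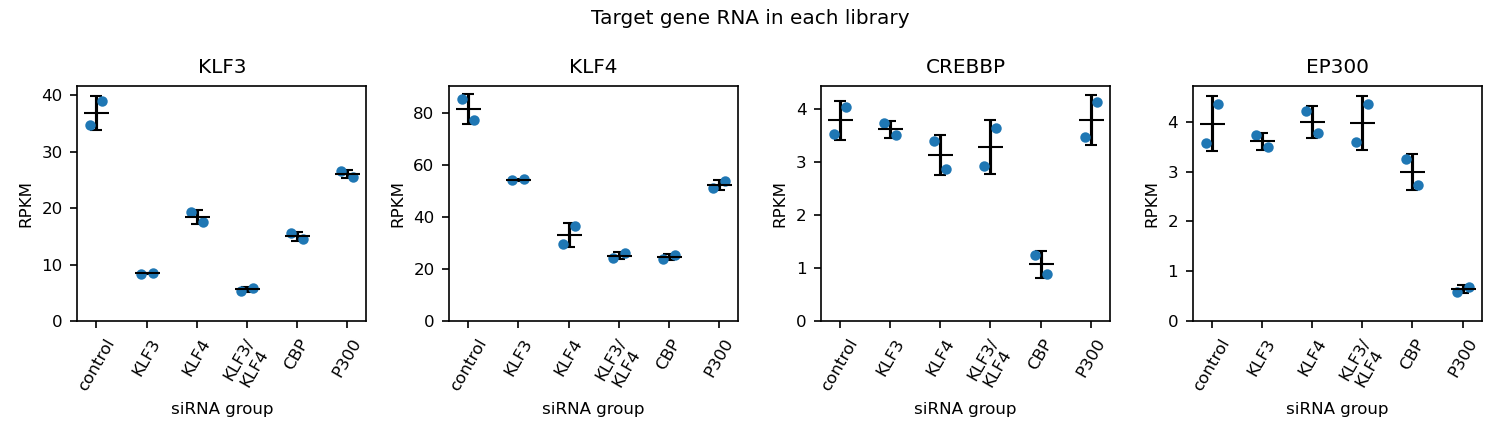
RPKM of KLF3, KLF4, CREBBP and EP300 in each library (points), with the group mean (horizontal line) and SD (whiskers, n = 2), for the 6 siRNA groups. KLF3 lies at 36.8 RPKM in control cells and at 8.47 RPKM after KLF3 knockdown.

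The largest falls after KLF3 knockdown included genes of the cornified layer. The antimicrobial protein gene S100A7 fell by 4.26 on the log2 scale (SE 0.11), the small proline-rich envelope genes SPRR2G and SPRR3 by 3.57 (SE 0.10) and 3.34 (SE 0.09), filaggrin 2 (FLG2) by 3.20 (SE 0.07) and cornifelin (CNFN) by 3.17 (SE 0.08). Loricrin (LOR), a main envelope protein, went from 8.29 to 0.0506 RPKM. The largest rises were in the collagen gene COL5A3 (log2 change 3.21, SE 0.09), the cyclin gene CCNA1 (3.17, SE 0.07), the galectin gene LGALS1 (2.89, SE 0.06), the homeobox gene MEIS3 (2.42, SE 0.08) and the exocytosis gene UNC13D (2.41, SE 0.07). In total 1942 genes rose and 3612 fell of 12067 tested, of which 417 and 706 changed at least 1.5-fold. The share that rose was 35.0%, and it was 45.6% with median-ratio scaling, so the balance of rises and falls rests on the scaling.

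In the late differentiation list 19 of 22 measured members fell after KLF3 knockdown and 0 rose (20 fell adjusted over the list alone), with a median of -1.34 and adjusted p = 1.25e-13 (adjusted p = 0.0833 with an estimated correlation). Of the late cornified envelope and small proline-rich genes 22 of 23 fell (22 adjusted over the list alone, adjusted p = 2.21e-12, and adjusted p = 0.0726 with an estimated correlation). Lipid barrier genes fell in 24 of 28 cases (24 adjusted over the list alone, adjusted p = 9.05e-11, and adjusted p = 0.0726 with an estimated correlation), among them the acylceramide pathway genes SDR9C7 (-1.73), CYP4F22 (-1.54) and PNPLA1 (-1.01). Early differentiation genes fell in 14 of 20 cases and rose in 2 (the same numbers adjusted over the list alone, adjusted p = 0.0029, and adjusted p = 0.427 with an estimated correlation). The calmodulin-like gene CALML5 fell by 2.24 while LY6D rose by 1.37. Inflammation and antimicrobial genes fell in 15 of 24 cases (15 adjusted over the list alone, adjusted p = 2.18e-06, and adjusted p = 0.172 with an estimated correlation), with the serpins SERPINB3 (-2.53) and SERPINB4 (-2.30).

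Cell cycle genes rose in 23 of 28 cases after KLF3 knockdown (25 adjusted over the list alone, adjusted p = 4.9e-12, and adjusted p = 0.0861 with an estimated correlation), from low levels: the topoisomerase gene TOP2A went from 0.158 to 1.10 RPKM. Interferon response genes rose in 23 of 31 cases (24 adjusted over the list alone, adjusted p = 3.75e-13, and adjusted p = 0.125 with an estimated correlation), MX1 by 0.97 and USP18 by 0.89. Basal layer genes rose in 15 of 21 cases and fell in 3 (the same adjusted over the list alone, adjusted p = 0.000117, and adjusted p = 0.172 with an estimated correlation). P-cadherin (CDH3) rose by 0.76 and the basal keratin gene KRT15 fell by 1.56. Matrix and wound edge genes rose in 11 of 19 cases (11 adjusted over the list alone, adjusted p = 4.16e-05, and adjusted p = 0.269 with an estimated correlation), with TGM2 (2.29) and vimentin, VIM (1.87), while 3 fell. Fibroblast markers had a median of 0.57 there (2 of 3 rose, adjusted p = 0.0507, and adjusted p = 0.172 with an estimated correlation). Within the KLF and SP family KLF12 rose by 1.01 and KLF8 by 1.15, while SP6 went from 5.97 to 2.94 RPKM. That family rose in 7 of 14 cases and fell in 2 (the same adjusted over the list alone, adjusted p = 0.0317, and adjusted p = 0.38 with an estimated correlation). That call was lost without control replicate 1 (adjusted p = 0.0598) and with a minimum of 5 RPKM (adjusted p = 0.29). The epidermal regulators OVOL1 (-1.55) and HOPX (-1.99) fell, but the transcription factor list did not pass the test (adjusted p = 0.228).

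Knockdown of KLF4 also lowered genes of the cornified layer. CNFN fell by 5.45 (SE 0.08), from 103 to 1.37 RPKM, SPRR2E by 4.96 (SE 0.12) and SPRR2A by 4.90 (SE 0.18). LCE3D (log2 change -4.80, SE 0.14) and SPRR2B (-4.19, SE 0.11) fell as well. The largest rises were in the collagen gene COL22A1 (3.59, SE 0.07), tenascin C, TNC (3.53, SE 0.08), the histone gene HIST1H3G (3.10, SE 0.19), the simple-epithelium keratin gene KRT19 (3.10, SE 0.09) and HIST1H3B (2.95, SE 0.14). In total 3710 genes rose and 2982 fell, of which 1013 and 904 changed at least 1.5-fold. The share that rose was 55.4%, and 46.3% with median-ratio scaling, so the balance rests on the scaling.

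After KLF4 knockdown, 23 of 23 late cornified envelope and small proline-rich genes fell (23 adjusted over the list alone, median -2.39, adjusted p = 4.17e-19), as did 26 of 28 lipid barrier genes (26 adjusted over the list alone, median -1.64, adjusted p = 4.17e-19). Both calls held with an estimated correlation (adjusted p = 0.0197). Among lipid barrier genes LIPN fell by 3.59, SDR9C7 by 3.42 and the glycolipid transfer gene GLTP by 2.91. Late differentiation genes fell in 21 of 22 cases (22 adjusted over the list alone, adjusted p = 1.59e-16, and adjusted p = 0.0581 with an estimated correlation), with filaggrin (FLG) going from 11.5 to 0.314 RPKM. Early differentiation genes fell in 18 of 20 cases (18 adjusted over the list alone, adjusted p = 3.29e-12, and adjusted p = 0.0937 with an estimated correlation), the envelope cross-linking enzyme gene TGM1 by 2.53 and SBSN by 2.25. Epidermal transcription factors fell in 16 of 27 cases and rose in 3 (adjusted p = 2.59e-06, and adjusted p = 0.0937 with an estimated correlation), HOPX by 2.99, OVOL1 by 2.36 and GRHL1 by 1.79. Inflammation genes fell in 16 of 24 cases and rose in 3 (adjusted p = 7.69e-07, and adjusted p = 0.126 with an estimated correlation), S100A8 by 2.61 and IL36RN by 2.21. Desmosome and tight junction genes fell in 12 of 22 cases and rose in 2 (adjusted p = 0.002, and adjusted p = 0.126 with an estimated correlation), with occludin (OCLN) at -1.01, PERP at -0.94 and claudin 7 (CLDN7) at 1.15. Stress keratins fell in 4 of 5 cases (adjusted p = 0.00363, and adjusted p = 0.233 with an estimated correlation). With p-values adjusted over the list alone, 16 transcription factor, 16 inflammation, 12 desmosome and 5 stress keratin genes fell.

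Cell cycle genes rose in 26 of 28 cases after KLF4 knockdown (adjusted p = 3.49e-12, and adjusted p = 0.0853 with an estimated correlation), with TOP2A at 1.74, CCNB1 at 1.59 and TPX2 at 1.41. Matrix and wound edge genes rose in 14 of 19 cases and fell in 3 (adjusted p = 1.29e-05, and adjusted p = 0.191 with an estimated correlation), with VIM at 2.60 and the activin gene INHBA at 1.80. Fibroblast markers had a median of 0.90 (2 of 3 rose, adjusted p = 0.0528, and adjusted p = 0.169 with an estimated correlation). Interferon genes rose in 26 of 31 cases and fell in 2 (adjusted p = 2.03e-06, and adjusted p = 0.191 with an estimated correlation), with BST2 at 1.43 and IFIT3 at 1.39. Basal layer genes rose in 12 of 21 cases and fell in 2 (adjusted p = 0.00313, and adjusted p = 0.215 with an estimated correlation). KRT15, which fell after KLF3 knockdown, rose by 1.36. Cholesterol synthesis genes fell in 16 of 24 cases and rose in 2 (adjusted p = 2.25e-05, and adjusted p = 0.191 with an estimated correlation), among them TM7SF2 (-2.33) and MSMO1 (-1.83). Adjusted over the list alone, 26 cell cycle, 14 matrix, 26 interferon and 12 basal layer genes rose and 16 cholesterol genes fell.

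In the double knockdown CNFN fell by 5.22 (SE 0.08), SPRR2E by 4.96 (SE 0.12), SPRR2G by 4.66 (SE 0.10), SPRR2A by 4.47 (SE 0.18) and the transcribed pseudogene WFDC21P by 4.12 (SE 0.08). LGALS1 rose by 3.91 (SE 0.06), from 20.4 to 321 RPKM, CCNA1 by 3.63 (SE 0.07), and the histone genes HIST1H3B and HIST1H3G each by 3.53 and HIST1H3F by 3.24. In total 3158 genes rose and 3086 fell, of which 906 and 801 changed at least 1.5-fold, and with median-ratio scaling 3110 rose and 3365 fell. Late cornified envelope and small proline-rich genes fell in 23 of 23 cases (23 adjusted over the list alone, median -2.02, adjusted p = 2.13e-18) and lipid barrier genes in 25 of 28 (27 adjusted over the list alone, adjusted p = 4.68e-17), both also past the threshold with an estimated correlation (adjusted p = 0.0213). Late differentiation genes fell in 21 of 22 cases (21 adjusted over the list alone, adjusted p = 4.02e-16, and adjusted p = 0.0554 with an estimated correlation) and early differentiation genes in 18 of 20 (18 adjusted over the list alone, adjusted p = 7.43e-10, and adjusted p = 0.0972 with an estimated correlation).

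Cell cycle genes rose in 26 of 28 cases in the double knockdown (median 1.24, adjusted p = 1.13e-14, and adjusted p = 0.0554 with an estimated correlation), with TOP2A going from 0.158 to 4.18 RPKM. Interferon genes rose in 29 of 31 cases (adjusted p = 7.58e-14, and adjusted p = 0.0972 with an estimated correlation), with MX2 at 2.11 and BST2 at 1.88. Basal layer genes rose in 18 of 21 cases and matrix genes in 15 of 19 (adjusted p = 3.58e-06 and 1.64e-08, and adjusted p = 0.0972 and 0.105 with an estimated correlation), with integrin ITGB4 at 0.86 and thrombospondin THBS1 at 1.63. Fibroblast markers, 3 of 3, rose as well (median 0.65, adjusted p = 0.0112, and adjusted p = 0.0972 with an estimated correlation). Inflammation genes fell in 16 of 24 cases (adjusted p = 5.44e-08, and adjusted p = 0.0972 with an estimated correlation), epidermal transcription factors in 14 of 27, with 4 rises (adjusted p = 0.000285, and adjusted p = 0.106 with an estimated correlation), and cholesterol genes in 15 of 24, with 3 rises (adjusted p = 6.55e-05, and adjusted p = 0.201 with an estimated correlation). OVOL1 fell by 2.80 and TM7SF2 by 2.37. Stress keratins fell in 4 of 5 cases (adjusted p = 0.0292, and adjusted p = 0.374 with an estimated correlation), a call lost with quantile normalization (adjusted p = 0.121), without control replicate 1 (0.0583) and without double knockdown replicate 1 (0.0507). Adjusted over the list alone, 26 cell cycle, 29 interferon, 18 basal layer and 17 matrix genes rose, and 17 inflammation, 15 transcription factor, 16 cholesterol and 4 stress keratin genes fell.

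**Figure D2:**
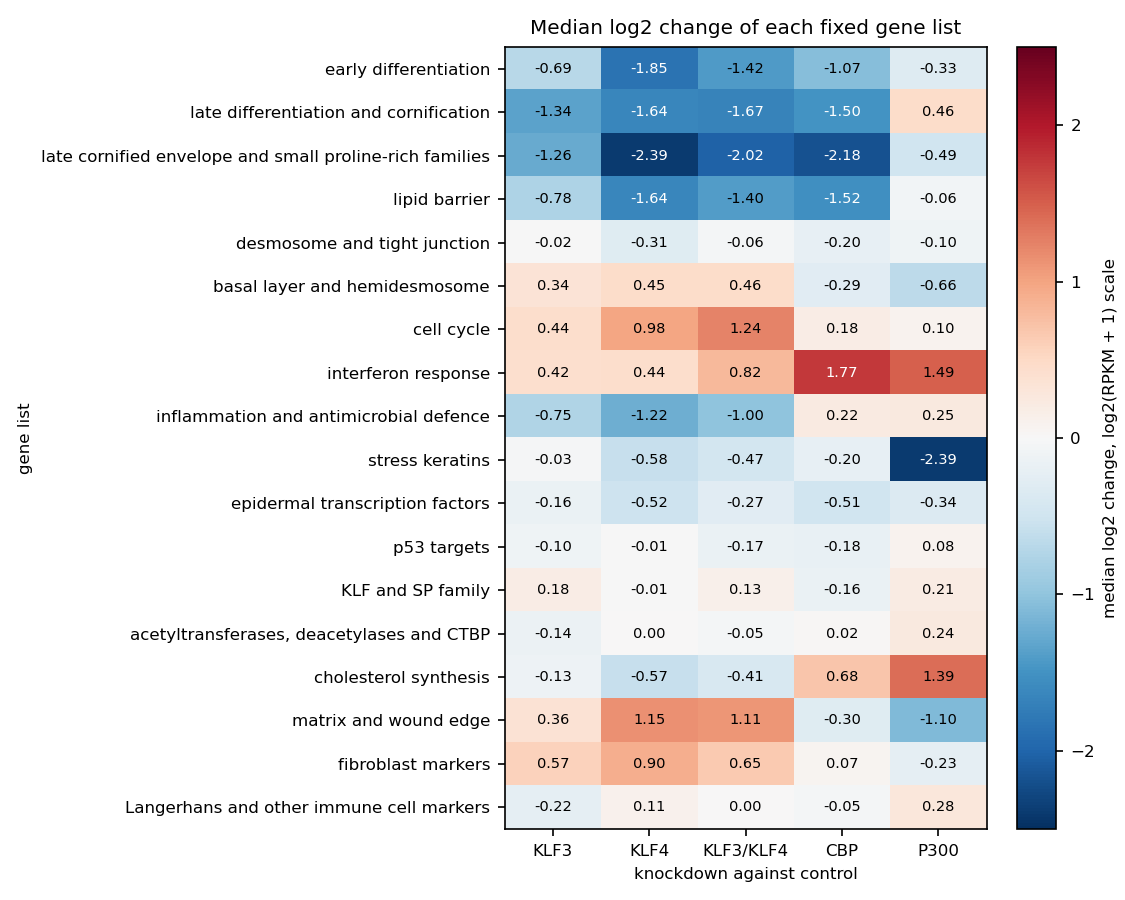
Median log2 change of the 18 tested gene lists (rows) in the 5 knockdowns against control (columns), on the log2(RPKM + 1) scale, with the value printed in each cell. Late differentiation genes have medians of -1.34, -1.64 and -1.67 after KLF3, KLF4 and double knockdown and 0.46 after P300 knockdown, where the median of all genes was 0.21.

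Set against the KLF3 knockdown, the double knockdown had higher keratin genes KRT75 (3.24, SE 0.10) and KRT19 (2.23, SE 0.09), COL22A1 (2.04, SE 0.07), TNC (1.83, SE 0.08) and SERPINA3 (1.78, SE 0.12). It had lower SPRR2A (-2.87, SE 0.18), SPRR2E (-2.73, SE 0.12), LCE3D (-2.05, SE 0.14), CNFN (-2.04, SE 0.08) and SPRR2B (-1.98, SE 0.11). In this comparison 2816 genes were higher and 1166 lower. The higher share was 70.7%, and 53.5% with median-ratio scaling. The count fell to 2453 without KLF3 knockdown replicate 1. All 23 late cornified envelope and small proline-rich genes were lower, as were 19 of 28 lipid barrier genes, with 1 higher (23 and 21 lower adjusted over the list alone, adjusted p = 7.33e-22 and 7.05e-16, and adjusted p = 0.0253 for both with an estimated correlation). Early differentiation genes were lower in 15 of 20 cases and higher in 1, late differentiation genes lower in 12 of 22, transcription factors lower in 14 of 27 and higher in 2, and cholesterol genes lower in 14 of 24 (adjusted p = 1.86e-14, 4.35e-08, 6.48e-09 and 6.48e-09, and adjusted p = 0.0783, 0.115, 0.0679 and 0.115 with an estimated correlation). Desmosome genes were lower in 8 of 22 cases and higher in 2, inflammation genes lower in 10 of 24 and higher in 5, and stress keratins lower in 3 of 5 (adjusted p = 0.000462, 0.00187 and 0.00269, and adjusted p = 0.0984, 0.258 and 0.252 with an estimated correlation). Cell cycle genes were higher in 25 of 28 cases, interferon genes in 20 of 31, matrix genes in 14 of 19, with 2 lower, and basal layer genes in 11 of 21, with 2 lower (adjusted p = 8.8e-12, 2.95e-07, 4.09e-06 and 0.045, and adjusted p = 0.0783, 0.191, 0.191 and 0.363 with an estimated correlation). The cell cycle call was lost with a minimum of 5 RPKM (adjusted p = 0.108). The basal layer call was lost with a minimum of 5 RPKM (adjusted p = 0.0729), median-ratio scaling (0.0556), only the groups compared (0.0963) and no intensity trend (0.0528), without either control library (0.0521 for both), without double knockdown replicate 2 (0.122), and without either CBP knockdown library (0.0548 and 0.0546). With p-values adjusted over the list alone, 16 early differentiation, 12 late differentiation, 18 transcription factor, 14 cholesterol, 8 desmosome, 10 inflammation and 3 stress keratin genes were lower, and 26 cell cycle, 22 interferon, 14 matrix and 11 basal layer genes higher.

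Against the KLF4 knockdown, the double knockdown had higher CRIP1 (2.07, SE 0.14), C10orf99 (2.02, SE 0.09), the chemokine gene CXCL14 (1.98, SE 0.14), decorin, DCN (1.76, SE 0.08), and COL5A3 (1.68, SE 0.09). KRT79 (-2.26, SE 0.11), TNC (-1.56, SE 0.08), KLF3 itself (-1.54, SE 0.08), KRT31 (-1.53, SE 0.10) and KRT15 (-1.51, SE 0.06) were lower. Here 1017 genes were higher and 1250 lower. The higher share was 44.9%, and 59.8% with median-ratio scaling, so the balance rests on the scaling. The count of 2267 fell to 1323 without KLF4 knockdown replicate 1, 1419 without KLF4 knockdown replicate 2, 1403 without double knockdown replicate 2 and 1369 when only the groups compared were fitted. Of 22 late differentiation genes 19 did not pass the test, and the list median was 0.03 (adjusted p = 0.377). Early differentiation genes were higher in 12 of 20 cases and lower in 2 (median 0.38), lipid barrier genes higher in 13 of 28 (median 0.13), and late cornified envelope and small proline-rich genes higher in 7 of 23 and lower in 1 (adjusted p = 1.65e-06, 1.54e-05 and 0.0187, and adjusted p = 0.243, 0.195 and 0.36 with an estimated correlation). Interferon genes were higher in 22 of 31 cases (25 adjusted over the list alone, adjusted p = 3.81e-15, and adjusted p = 0.195 with an estimated correlation).

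Also against the KLF4 knockdown, cell cycle genes were higher in the double knockdown in 14 of 28 cases and lower in 2, and the KLF and SP family higher in 7 of 14 (adjusted p = 3.91e-05 and 5.41e-05, and adjusted p = 0.243 and 0.195 with an estimated correlation). With a minimum of 5 RPKM the cell cycle median of 0.24 turned to -0.11 (adjusted p = 0.599). Transcription factors were higher in 9 of 27 cases and lower in 1, p53 targets lower in 10 of 22 and higher in 2, and desmosome genes higher in 9 of 22 and lower in 3 (adjusted p = 0.00537, 0.00649 and 0.0113, and adjusted p = 0.246, 0.195 and 0.243 with an estimated correlation). Basal layer genes were higher in 9 of 21 cases and lower in 2, and stress keratins higher in 3 of 5 (adjusted p = 0.0376 for both, and adjusted p = 0.443 for both with an estimated correlation). Quantile normalization ended the calls for late cornified envelope (adjusted p = 0.148), desmosome (0.151), basal layer (0.95) and stress keratin genes (0.248), with a median of 0 for the last 2, and median-ratio scaling that for late cornified envelope genes (0.0993). A minimum of 5 RPKM ended those for basal layer (adjusted p = 0.103) and stress keratin genes (0.0638), and fitting only the groups compared that for stress keratins (0.0559). Calls were also lost without KLF4 knockdown replicate 1 for stress keratins (adjusted p = 0.098), without KLF4 knockdown replicate 2 for late cornified envelope (0.0805) and basal layer genes (0.0858), and without double knockdown replicate 2 for basal layer (0.105), stress keratin (0.0682) and transcription factor genes (0.0842). With p-values adjusted over the list alone, 13 early differentiation, 13 lipid barrier, 7 late cornified envelope, 16 cell cycle, 8 KLF and SP family, 9 transcription factor, 11 desmosome, 9 basal layer and 3 stress keratin genes were higher and 12 p53 targets lower.

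The double knockdown changed differentiation genes by less than the sum of both single knockdowns. On the log2 scale the protease gene ASPRV1 departed upward from the sum by 3.55 (SE 0.20), S100A7 by 3.55 (SE 0.16), CNFN by 3.41 (SE 0.12), FLG2 by 3.22 (SE 0.10) and SPRR3 by 3.21 (SE 0.12). Values cannot lie under 0 RPKM, so the single falls alone force a departure of at least 2.56 for ASPRV1, 1.18 for S100A7, 1.93 for CNFN, 3.13 for FLG2 and 0.67 for SPRR3. HIST1H3B (-1.80, SE 0.20), the cytokine gene IL32 (-1.75, SE 0.19), HIST1H3G (-1.72, SE 0.27), TNC (-1.70, SE 0.11) and VIM (-1.70, SE 0.14) departed downward. All 23 late cornified envelope and small proline-rich genes, 26 of 28 lipid barrier genes and 19 of 22 late differentiation genes departed upward (adjusted p = 8.97e-19, 1.45e-20 and 1.63e-19), and these calls held with an estimated correlation (adjusted p = 0.0216, 0.0216 and 0.0384). Adjusted over the list alone, 23, 27 and 20 members departed upward. The same floor forces some departure in 16 of the 23, 9 of the 28 and 17 of the 22 genes, so these list tests carry that limit. In total 2005 genes departed upward, 133 of them with a departure in part forced by the floor, and 1142 downward. The upward share was 63.7%, and 51.0% with quantile normalization, and the count of 3147 fell to 1887 without control replicate 2.

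**Figure D3:**
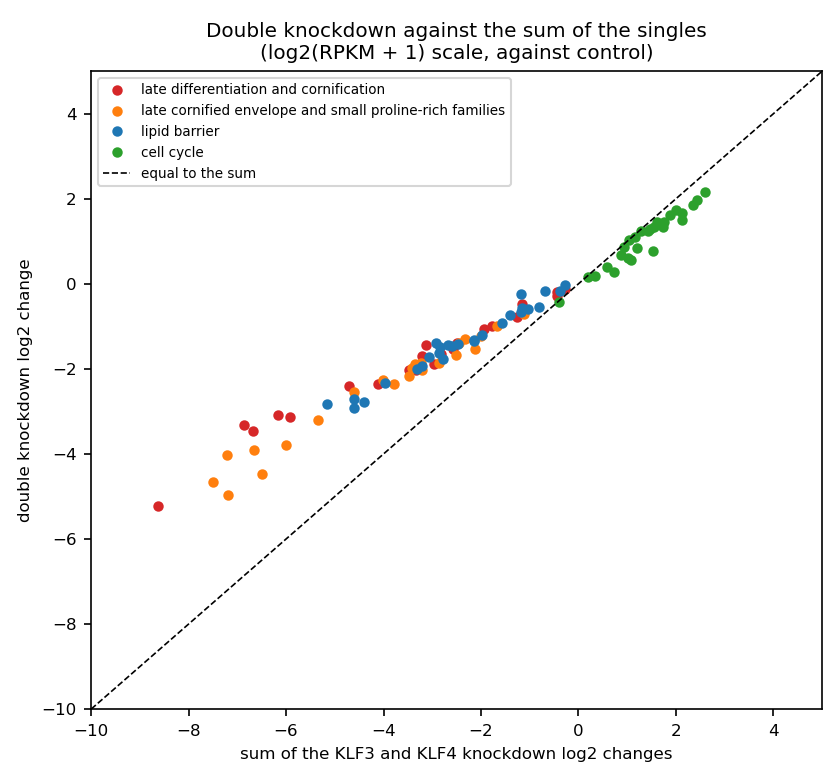
Log2 change in the double knockdown (vertical axis) against the sum of the log2 changes of both single knockdowns (horizontal axis), log2(RPKM + 1) scale, for the members of 4 gene lists (1 point per gene). The dashed line marks equality, and the late differentiation genes have a median departure from it of 1.24, in part forced by the floor of the scale in 17 of 22 genes.

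After CBP knockdown the envelope gene SPRR3 was among the genes that fell most, and interferon-induced genes were among those that rose most. S100P fell by 6.25 (SE 0.10), from 217 to 1.86 RPKM, the glutathione-degrading enzyme gene CHAC1 by 5.14 (SE 0.06), and SPRR3 by 4.88 (SE 0.09). Stanniocalcin 2, STC2 (-4.98, SE 0.08), and KRT23 (-4.46, SE 0.09) also fell. The largest rises were in the interferon-induced genes IFIT1 (3.48, SE 0.10), IFIT3 (3.29, SE 0.08) and CMPK2 (2.92, SE 0.07), the acute-phase gene SAA1 (3.24, SE 0.11) and LY6D (3.13, SE 0.09). In total 5066 genes rose and 3161 fell, of which 1751 and 1255 changed at least 1.5-fold. The share that rose was 61.6%, and 49.0% with median-ratio scaling, which moved the median of all genes from 0.11 to -0.00449.

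After CBP knockdown 23 of 23 late cornified envelope and small proline-rich genes fell (23 adjusted over the list alone, median -2.18, adjusted p = 3.82e-16), as did 26 of 28 lipid barrier genes (26 adjusted over the list alone, adjusted p = 1.34e-14), both also with an estimated correlation (adjusted p = 0.0319). LIPN fell by 3.68 and the lipoxygenase gene ALOX12B by 3.02. Late differentiation genes fell in 21 of 22 cases (adjusted p = 1.34e-14, and adjusted p = 0.0771 with an estimated correlation), the protease inhibitor gene SPINK5 by 3.18, and early differentiation genes in 15 of 20, with 3 rises (16 falls adjusted over the list alone, adjusted p = 6.3e-07, and adjusted p = 0.264 with an estimated correlation), desmocollin 1 (DSC1) by 3.41. Interferon genes rose in 30 of 31 cases (median 1.77, adjusted p = 1.01e-13, and adjusted p = 0.148 with an estimated correlation), with the chemokine gene CXCL10 at 2.59 and USP18 at 2.74. Cholesterol synthesis genes rose in 21 of 24 cases (adjusted p = 4.24e-05, and adjusted p = 0.296 with an estimated correlation), IDI1 by 1.35 and LSS by 1.18. Epidermal transcription factors fell in 16 of 27 cases and rose in 3 (adjusted p = 4.24e-05, and adjusted p = 0.148 with an estimated correlation), HOPX by 2.63 and CEBPA by 1.74. Adjusted over the list alone, 21 late differentiation and 16 transcription factor genes fell and 30 interferon and 21 cholesterol genes rose.

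Basal layer genes fell in 12 of 21 cases and rose in 5 after CBP knockdown (adjusted p = 0.00746, and adjusted p = 0.345 with an estimated correlation), integrin ITGA2 by 1.27 and the laminin genes LAMA3 and LAMB3 by 1.13 and 1.05. Desmosome and tight junction genes fell in 11 of 22 cases and rose in 5 (adjusted p = 0.0363, and adjusted p = 0.296 with an estimated correlation), a call lost with quantile normalization (adjusted p = 0.092) and without control replicate 2 (0.0515). Matrix genes fell in 11 of 19 cases and rose in 5 (adjusted p = 0.0482, and adjusted p = 0.632 with an estimated correlation). Fibronectin (FN1) fell by 2.05 and PLAU rose by 2.30. The matrix call was lost with median-ratio scaling (adjusted p = 0.0857), quantile normalization (0.122) and a minimum of 5 RPKM (0.0857), without control replicate 2 (0.0585), without CBP knockdown replicate 1 (0.0996), and without either P300 knockdown library (0.0534 and 0.0535). With p-values adjusted over the list alone, 12 basal layer, 11 desmosome and 11 matrix genes fell. Inflammation genes went both ways, 11 up and 11 down of 24, with a median of 0.22, a mean of -0.03 and adjusted p = 0.666. Cell cycle genes rose in 14 of 28 cases with adjusted p = 0.282, and with quantile normalization the list passed (adjusted p = 0.0288).

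After P300 knockdown more late differentiation genes rose than fell, as among all 12067 genes tested, and the list did not pass the test. Of its 22 members 14 rose and 5 fell (the same adjusted over the list alone, median 0.46, adjusted p = 0.788). FLG2 rose by 3.21 (SE 0.07), from 10.7 to 107 RPKM, and SERPINB12 by 3.40 (SE 0.07), whereas the protease gene KLK5 fell by 3.78 (SE 0.08). The other largest rises were in the elastase inhibitor gene PI3 (3.84, SE 0.09), HRASLS2 (3.68, SE 0.09), osteopontin (SPP1), which was listed at 0 in both control libraries and had 9.59 RPKM after knockdown, and HSD17B2 (3.33, SE 0.09). The largest falls were in SPRR2A (-5.18, SE 0.18), CHAC1 (-5.00, SE 0.06), the serine synthesis gene PSAT1 (-4.76, SE 0.07), asparagine synthetase, ASNS (-4.69, SE 0.06), and TRIB3 (-4.63, SE 0.07). In total 6222 genes rose and 2461 fell, of which 2456 and 989 changed at least 1.5-fold. The share that rose was 71.7%, and 51.6% with median-ratio scaling, which moved the median of all genes from 0.21 to 0.0132.

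Stress keratins fell in 4 of 5 cases after P300 knockdown (median -2.39, adjusted p = 2.88e-05, and adjusted p = 0.224 with an estimated correlation), among them KRT6B (-3.30) and KRT16 (-2.39). Basal layer genes fell in 17 of 21 cases (adjusted p = 6.99e-10, and adjusted p = 0.224 with an estimated correlation), with KRT15 going from 21.1 to 6.80 RPKM, and LAMB3 and integrin ITGA3 both at -1.48. Matrix genes fell in 13 of 19 cases and rose in 4 (14 falls adjusted over the list alone, adjusted p = 5.63e-06, and adjusted p = 0.224 with an estimated correlation), VIM by 2.48, while SPARC rose by 1.48. Late cornified envelope and small proline-rich genes fell in 13 of 23 cases and rose in 7 (adjusted p = 0.000614, and adjusted p = 0.224 with an estimated correlation), SPRR2D by 2.87 and SPRR1A by 2.59. Epidermal transcription factors fell in 15 of 27 cases and rose in 4 (adjusted p = 4.35e-05, and adjusted p = 0.224 with an estimated correlation), OVOL1 by 2.43, whereas HOPX rose by 1.43. Interferon genes rose in 29 of 31 cases (median 1.49, adjusted p = 1.8e-08, and adjusted p = 0.224 with an estimated correlation), IFIT3 by 3.27 and USP18 by 2.59. Cholesterol synthesis genes rose in 23 of 24 cases (median 1.39, adjusted p = 2.96e-07, and adjusted p = 0.224 with an estimated correlation), MVD by 2.41 and IDI1 by 2.09. Early differentiation and desmosome genes fell in 11 of 20 and 9 of 22 cases and rose in 6 and 5 (adjusted p = 0.005 and 0.0179), calls lost with an estimated correlation (adjusted p = 0.556 and 0.224) and with quantile normalization (adjusted p = 0.0818 and 0.0598). The lipid barrier list had 11 rises and 12 falls of 28 (median -0.06, mean 0.06, adjusted p = 0.121), and 10 rises and 16 falls both with median-ratio scaling (median -0.30) and with quantile normalization (median -0.25), with the ceramide enzyme genes DEGS2 at 2.07 and FA2H at 1.31. With p-values adjusted over the list alone, 4 stress keratin, 17 basal layer, 13 late cornified envelope, 15 transcription factor, 11 early differentiation and 9 desmosome genes fell, and 29 interferon and 23 cholesterol genes rose.

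Lists not described above for a knockdown did not pass the test. For p53 targets the adjusted p was 0.531, 0.819, 0.0573, 0.282 and 0.754 after KLF3, KLF4, double, CBP and P300 knockdown, with the double knockdown passing with no filter (adjusted p = 0.0328), without control replicate 2 (0.0342) and without double knockdown replicate 2 (0.0455), and for acetyltransferases, deacetylases and CTBP it was 0.347, 0.469, 0.436, 0.666 and 0.788. For the KLF and SP family it was 0.416, 0.308, 0.235 and 0.90 after KLF4, double, CBP and P300 knockdown. After P300 knockdown the p53 target TP53I3 rose by 2.27 and SESN2 fell by 2.19. Of markers of other cell types, MITF was the highest melanocyte gene, at no more than 0.972 RPKM in any library, and the macrophage gene CD68 was the highest immune gene, at no more than 7.85 RPKM. CD68, the 1 tested member of the immune list, fell after KLF3 knockdown (-0.22, adjusted p = 0.0253) and rose after P300 knockdown (0.28, adjusted p = 0.00429). Both calls were lost with median-ratio scaling (adjusted p = 0.0861 and 0.478) and quantile normalization (0.129 and 0.363), and the KLF3 call also without control replicate 2 (0.188) or either KLF3 library (0.0619 and 0.118). The fibroblast gene DCN was 1.28 ± 0.0133 RPKM in control cells, 8.11 ± 0.908 after KLF3 knockdown, 13.5 ± 1.04 in the double knockdown and 9.85 ± 0.280 after P300 knockdown, while the collagen gene COL1A2 stayed at or below 0.485 RPKM in every library. COL1A1, also high in fibroblasts, was 7.27 ± 0.472 RPKM in control cells, 11.3 ± 0.823 after KLF3 knockdown, 10.9 ± 2.74 in the double knockdown and 2.91 ± 0.835 after P300 knockdown, and FBLN1 was 2.09 ± 0.0551 in control cells, 4.89 ± 0.102 after KLF4 knockdown and 3.85 ± 0.408 in the double knockdown. The rise of COL1A1 after KLF3 knockdown (0.57, adjusted p = 0.0278) was lost without either control library (adjusted p = 0.118 and 0.0762) or either KLF3 library (0.0663 and 0.131). Its rise in the double knockdown (0.51, adjusted p = 0.0408) was lost with a pseudocount of 0.1 (adjusted p = 0.052), with no filter (0.0633), without either control library (0.158 and 0.0885), without either KLF3 library (0.0539 and 0.054) and without double knockdown replicate 2 (0.306). The fibroblast list, with 3 measured members, passed for KLF3 knockdown when only the groups compared were fitted (adjusted p = 0.0228), with a minimum of 5 RPKM (0.0138), and without control replicate 2 (0.0442), KLF3 knockdown replicate 2 (0.0261), either double knockdown library (0.0482 and 0.0479) or either CBP knockdown library (0.0449 and 0.0448). For KLF4 knockdown it passed with a pseudocount of 0.1 (adjusted p = 0.0485), with no filter (0.0122), with median-ratio scaling (0.038), with only the groups compared (0.0364), and without KLF4 knockdown replicate 1 (0.0459) or either double knockdown library (0.0464 and 0.0462).

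CBP and P300 knockdown were also compared directly. After CBP knockdown KRT75 (4.19, SE 0.10), TNC (3.69, SE 0.08), the cyclin gene CCND2 (3.55, SE 0.06), LY6D (3.55, SE 0.09) and PLAU (3.53, SE 0.08) were higher than after P300 knockdown. S100P (-7.22, SE 0.10), FLG2 (-6.31, SE 0.07), PI3 (-5.99, SE 0.09), SPRR3 (-5.98, SE 0.09) and the keratin gene KRT77 (-5.06, SE 0.16) were lower. Late differentiation genes were lower in 20 of 22 cases and lipid barrier genes in 24 of 28 (adjusted p = 1.33e-08 and 1.24e-07, and adjusted p = 0.313 and 0.292 with an estimated correlation). Cholesterol synthesis genes were lower in 20 of 24 cases and stress keratins higher in 4 of 5 (adjusted p = 0.000569 for both, and adjusted p = 0.544 and 0.383 with an estimated correlation). Late cornified envelope and small proline-rich genes were lower in 17 of 23 cases and higher in 4, and early differentiation genes lower in 14 of 20 and higher in 3 (adjusted p = 0.000569 and 0.0109, and adjusted p = 0.373 and 0.707 with an estimated correlation). Basal layer genes were higher in 12 of 21 cases, and interferon genes higher in 16 of 31 and lower in 4 (adjusted p = 0.000188 and 0.000769, and adjusted p = 0.373 and 0.62 with an estimated correlation). With p-values adjusted over the list alone, 20 late differentiation, 24 lipid barrier, 20 cholesterol, 17 late cornified envelope and 14 early differentiation genes were lower, and 4 stress keratin, 11 basal layer and 16 interferon genes higher. In total 3014 genes were higher and 4873 lower. The higher share was 38.2%, and 51.9% with quantile normalization.

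Genes that fell with both KLF3 and CBP knockdown numbered 1276, where independent lists would share 946, and 956 rose with both, where independent lists would share 815. Another 1789 went in opposite directions. The covariance of the fold changes across genes was 0.0742, against 0.00418 for simulated unchanged groups that share the same controls, in which no gene was called in both. Few calls can arise where no gene changes, so that count cannot tell how many shared calls the controls cause. The correlation was 0.304, against 0.503 in those simulations, which the shared controls raise when nothing changes. For KLF3 and P300 knockdown the covariance was 0.00824, higher than the simulated value by 0.00407, with 889 shared falls and 968 shared rises (737 and 1001 for independent lists). KLF4 and CBP knockdown shared 1286 falls and 1938 rises (781 and 1558 for independent lists), with a covariance of 0.123, and double and CBP knockdown shared 1267 falls and 1700 rises (808 and 1326 for independent lists), with a covariance of 0.124. With P300 knockdown, KLF4 knockdown shared 751 falls and 1850 rises (608 and 1913 for independent lists, covariance 0.00423), double knockdown 785 and 1617 (629 and 1628, covariance 0.0193) and CBP knockdown 1388 and 3608 (645 and 2612, covariance 0.177). The genes that fell most in both KLF3 and CBP knockdown were SPRR2G, SPRR3, CNFN, FLG2 and LOR. After P300 knockdown SPRR2G, SPRR3, FLG2 and LOR instead rose, by 1.09, 1.10, 3.21 and 1.90, and CNFN differed by 0.28, close to the median of all genes, 0.21. FGFBP1, CXCL14, IFITM2, FAM213A and ECHDC3 rose most in both. Of the 1276 genes that fell with KLF3 and CBP knockdown, 573 fell, 407 rose and 296 did not pass the test after P300 knockdown, and of the 956 that rose with both, 635 rose, 102 fell and 219 did not pass. Of all 12067 genes tested, 2461 fell and 6222 rose after P300 knockdown. The genes shared by KLF3 and CBP knockdown went the same way after P300 knockdown more often than all genes did. But of all 3161 genes that fell after CBP knockdown 43.9% also fell after P300 knockdown, and of all 5066 that rose 71.2% also rose. Genes shared with KLF3 knockdown lay near that share for falls and under it for rises, so the excess is not particular to them. In an alternative chosen after seeing the data, each comparison was set against its own control library, which was assumed to vary like the other groups. KLF3 and CBP knockdown then shared 969 falls and 682 rises (571 and 513 for independent lists, covariance 0.0790) with control replicate 1 used for KLF3, and 1025 and 665 (773 and 613, covariance 0.0594) with control replicate 2 used for KLF3. For KLF3 and P300 knockdown the covariance became 0.0175 and -0.0111, and for KLF4 and P300 knockdown 0.0115 and -0.0131, so their sign rested on the control library. Where both comparisons use the same controls, part of the shared calls may come from them.

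**Figure D4:**
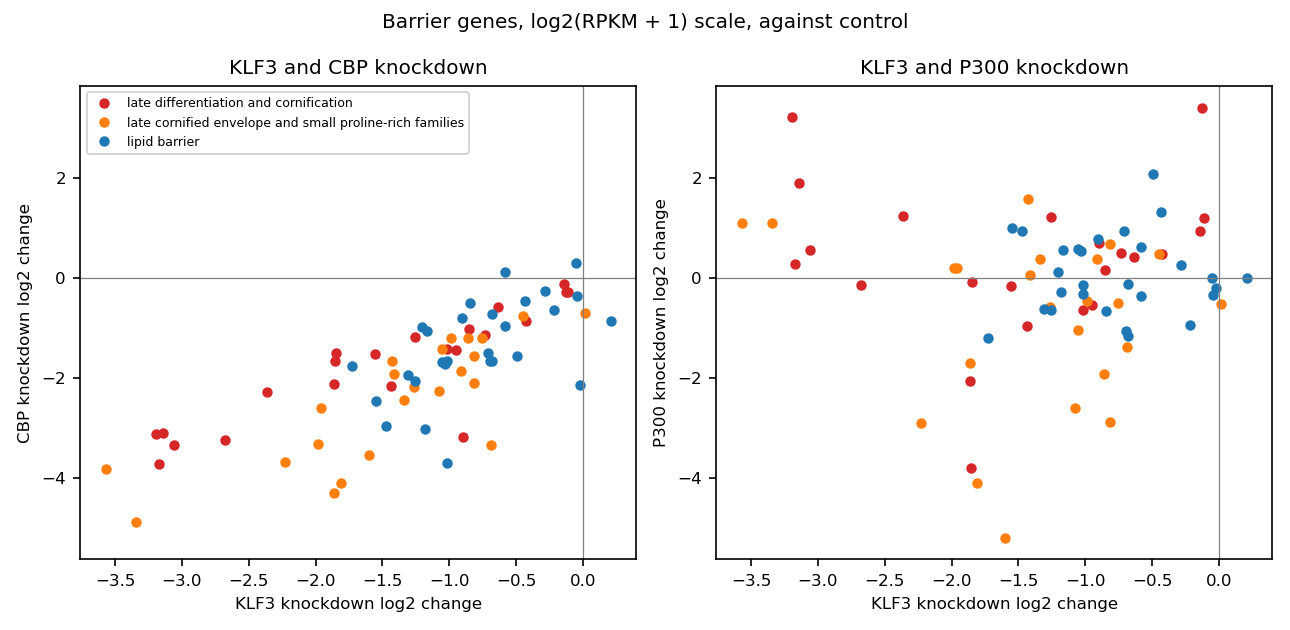
Log2 change after CBP knockdown (left) and P300 knockdown (right) against the change after KLF3 knockdown, log2(RPKM + 1) scale, for late differentiation, late cornified envelope and small proline-rich, and lipid barrier genes (1 point per gene). FLG2 lies at -3.10 on the left and at 3.21 on the right.

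The authors' deposited tables list 986, 2037, 1699, 2723 and 3038 genes for KLF3, KLF4, double, CBP and P300 knockdown. Of 563 genes that fell with KLF3 knockdown in the authors' deposited tables, 282 (50.1%) also fell with CBP knockdown and 133 (23.6%) with P300 knockdown. Of 423 genes that rose with KLF3 knockdown in the authors' deposited tables, 135 (31.9%) also rose with CBP knockdown and 109 (25.8%) with P300 knockdown. Genes listed in opposite directions numbered 40 for KLF3 with CBP knockdown and 141 for KLF3 with P300 knockdown. For KLF4 knockdown, too, the authors' deposited tables share more with CBP knockdown. Of 772 falls, 367 (47.5%) were shared with CBP and 145 (18.8%) with P300 knockdown, and of 1265 rises 329 (26.0%) and 240 (19.0%). Opposite directions were listed for 98 genes with CBP and 275 with P300 knockdown. These lists share the control libraries, and the overlap of independent lists was not computed for them. In all, the authors' deposited tables list 1138 falls and 1585 rises for CBP knockdown and 963 and 2075 for P300 knockdown. The signed folds of the authors' deposited tables matched the ratio of mean RPKM within 1% for 100% of the genes checked. Of the genes in the authors' deposited tables that passed the filter used here, at least 99.7% per table were also called here in the same direction. Another 319, 763, 591, 825 and 985 genes listed for KLF3, KLF4, double, CBP and P300 knockdown were not tested here. Both sets of calls rest on the same libraries. In the authors' deposited table for KLF3 knockdown, KLF3 has a fold of -4.34.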

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

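The test of whether the KLF3 and KLF4 knockdowns add up, and the list tests on it, were planned, whereas the tests of knockdown strength and of the control libraries as a whole cause were chosen only after the results were seen. The effect of KLF3 siRNA differed between cells with and without KLF4 siRNA, by the interaction term in limma, for 3147 genes. Median departures from additivity were 1.43 for late cornified envelope and small proline-rich genes, 1.24 for late differentiation, 1.04 for lipid barrier (where the floor of the scale forces some departure in 16 of 23, 17 of 22 and 9 of 28 genes), 0.86 for early differentiation, 0.69 for inflammation and 0.31 for epidermal transcription factors. With an estimated correlation the first 3 calls held (adjusted p = 0.0216, 0.0384 and 0.0216) and the other 3 were lost (adjusted p = 0.162, 0.162 and 0.188). Medians were -0.26 for cell cycle, -0.25 for matrix and wound edge, -0.14 for basal layer and -0.13 for interferon genes, and all 4 calls were lost with an estimated correlation (adjusted p = 0.162, 0.34, 0.437 and 0.522). The last 2 calls were lost without control replicate 1 (adjusted p = 0.0537 and 0.0522), and the basal layer call also without double knockdown replicate 1 (0.05) and with no filter (0.0512). Single genes departed by 3.55 (ASPRV1), 3.55 (S100A7), 3.41 (CNFN), 3.22 (FLG2) and 3.21 (SPRR3), of which the floor at 0 RPKM alone forces 2.56, 1.18, 1.93, 3.13 and 0.67, and by -1.80 (HIST1H3B), -1.75 (IL32), -1.72 (HIST1H3G), -1.70 (TNC) and -1.70 (VIM).

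The upward departure of differentiation genes was weighed against technical explanations. The log2(RPKM + 1) scale has a floor, but among the 25 of 73 members whose additive expectation was at least 1 RPKM, the median departure on plain log2 RPKM was 1.11 with a lower quartile of 0.69, and 25 of 25 departed upward, which argues against the floor for these genes. For the other 48 members the floor stays open. A weaker knockdown in the double treatment stays open. RNA of KLF3 (-0.51, upper 95% bound -0.34) and KLF4 (-0.37, upper bound -0.18) was lower in the double than in the single knockdowns. But KLF4 knockdown alone lowered KLF3 RNA by 49.8%, and KLF3 knockdown alone lowered KLF4 RNA by 33.1%. The lower RNA therefore cannot tell how well each siRNA worked in the double treatment. KLF3 RNA itself also departed upward from additivity in limma (0.45, adjusted p = 0.0109), while KLF4 did not pass (0.20, adjusted p = 0.265). No biological explanation was tested, and differences between cultures stay open.

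Interferon genes rose in all 5 knockdowns, with list medians from 0.42 to 1.77, and these calls were lost with an estimated correlation (adjusted p = 0.125, 0.191, 0.0972, 0.148 and 0.224 after KLF3, KLF4, double, CBP and P300 knockdown). Low values in the 2 control libraries as the whole cause are argued against by the direct comparison of double and KLF3 knockdown, where 20 of 31 members rose with a median of 0.41 (adjusted p = 0.191 for the list with an estimated correlation). The lowest median, 0.42, exceeded the largest difference between replicates of a group, 0.0953, but nothing says that replicates came from separate cultures, so the bound set beforehand was wrong and chance differences between cultures stay open. A condition shared by both control libraries stays open for the common part, because every comparison against control uses them, and so may a response to siRNA that differs between sequences and amounts, which were not analysed here.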

How the results depend on the processing

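Rescaling without 3 small RNAs, the crossed pairing and the split controls were chosen after seeing the data; the other alternatives were planned. Named genes and targets kept their direction wherever they were called. Between double and KLF4 knockdown the cell cycle median turned from 0.24 to -0.11 with a minimum of 5 RPKM (adjusted p = 0.599), and the respiratory chain median, -0.00358 with all libraries, ranged from -0.0537 to 0.0703 when 1 library was left out, with a call (adjusted p = 0.0117) at the upper end, without double knockdown replicate 2. The cause was not tested. A fold minimum of 1.5 lowered the counts to 1123 (KLF3), 1917 (KLF4), 1707 (double), 3006 (CBP), 3445 (P300), 720 (double against KLF3), 353 (double against KLF4), 928 (additivity), 2928 (CBP against P300) and 458 (shared by KLF3 and CBP), by construction. Fitting only the groups compared gave 1369 for double against KLF4, with fewer samples in the fit. Each count computed under another setting that keeps every library stayed within 1.5 times, where rescaling was run only for the 5 knockdowns against control, the crossed pairing for 3 of them and the split controls only for the shared genes (1651 and 1690). Leaving out 1 library, where the lone sample is assumed to vary like the other groups, gave 3769 to 5542 (KLF3), 5411 to 6688 (KLF4), 4962 to 6143 (double), 7185 to 8242 (CBP), 7582 to 8697 (P300), 2453 to 3947 (double against KLF3), 1323 to 2187 (double against KLF4), 1887 to 3056 (additivity), 6768 to 7911 (CBP against P300) and 1565 to 2236 (shared). The cause was not tested beyond the smaller number of samples.

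Deviations of same-numbered libraries correlated between -0.39 and 0.39 over 15 pairs of groups, 3 above 0.1 and 6 under -0.1, so the numbers were not taken to pair the samples. KLF4, double and P300 knockdown deviated together (0.39, 0.27 and 0.34) and opposite to the controls (-0.39, -0.23 and -0.30), a structure whose cause was not tested. With a replicate block the counts were 5441 (KLF3), 6596 (KLF4), 6124 (double), 8176 (CBP) and 8638 (P300), and the block changed no target, named-gene or list call against control. With the control numbers crossed the counts were 6867 (KLF4), 6424 (double) and 8817 (P300).

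The lists called against control, 10, 13, 13, 10 and 9 of 18 for KLF3, KLF4, double, CBP and P300, became 0, 2, 2, 2 and 0 with an estimated correlation. With fry, which does not compare a list with other genes, 16 were called for KLF3 and 18 for P300. Of 330 named gene results, calls were lost on leaving out a library only for COL1A1 (KLF3 and double), KRT6A (CBP), CD68 (KLF3) and FBLN1 (P300). What depth limits was not tested, since relative depths were known only up to a simple ratio.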

Other observations

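The gene groups in this part and the members named were chosen after seeing the data, and the test of relative depth after the result was seen. The adjusted p-values of these groups are over 54 tests, all groups and comparisons together. Amino acid response genes, known targets of ATF4 of which only some supply amino acids, fell in 31 of 31 cases after CBP knockdown (median -2.08). After P300 knockdown 29 of 31 fell (median -2.48), where SLC7A1 and ATF5 did not pass the test. Without the leading genes whose fall prompted the list, 22 members remained, of which 22 and 20 fell (adjusted p = 1.43e-16 and 2.44e-18 by camera, and adjusted p = 0.0470 and 0.0468 with an estimated correlation). The list went the other way after KLF3 knockdown, with 10 rises and 3 falls (median 0.11, adjusted p = 0.00522, and adjusted p = 0.444 with an estimated correlation). After KLF4 knockdown 13 rose and 2 fell (median 0.16, adjusted p = 0.0525), and after double knockdown 7 rose and 4 fell (median 0.0545, adjusted p = 0.472). The KLF4 list passed with a minimum of 5 RPKM (adjusted p = 0.0276), quantile normalization (0.00811) and only the groups compared (0.0356), and without control replicate 1 (0.0469), either KLF3 library (0.0448 and 0.0465), KLF4 knockdown replicate 2 (0.0432) or either CBP library (0.0432 and 0.0445). ATF4 itself fell by 1.59 and 1.54, DDIT3 by 3.38 and 3.04, and MTHFD2 by 2.86 and 2.76. Cytosolic aminoacyl-tRNA synthetase genes fell in 12 of 17 cases and rose in 4 in both (adjusted p = 2.56e-05 and 6.69e-07, and adjusted p = 0.357 and 0.32 with an estimated correlation). Respiratory chain and ATP synthase genes rose in 76 of 85 cases after CBP and 82 of 85 after P300 knockdown (adjusted p = 3.45e-12 and 9.61e-09, and adjusted p = 0.40 and 0.484 with an estimated correlation).

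Histone genes rose in 51, 53 and 54 of 66 cases after KLF3, KLF4 and double knockdown (adjusted p = 1.58e-19, 3.79e-14 and 3.73e-17, and adjusted p = 0.255, 0.32 and 0.255 with an estimated correlation), with values uncertain between copies. After CBP knockdown 30 rose and 7 fell (adjusted p = 0.299, and 0.0466 without CBP knockdown replicate 1), and after P300 knockdown 30 rose and 8 fell (adjusted p = 0.748). From additivity 40 of 66 departed downward (median -0.54, adjusted p = 1.88e-17, and adjusted p = 0.255 with an estimated correlation). Antigen presentation genes of MHC class I rose in 10, 12 and 11 of 13 cases after KLF3, KLF4 and double knockdown (adjusted p = 6.81e-07, 0.000378 and 2.85e-05, and adjusted p = 0.32, 0.40 and 0.339 with an estimated correlation), in 12 after CBP knockdown (median 1.04, adjusted p = 2.85e-05, and adjusted p = 0.339 with an estimated correlation) and in 6, with 3 falls, after P300 knockdown, where the median of 0.21 became -0.04 with median-ratio scaling. The direct comparison was higher after CBP knockdown in 11 of 13 (adjusted p = 1.94e-05, and adjusted p = 0.339 with an estimated correlation).

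The fall of amino acid response genes was weighed against technical explanations. With median-ratio scaling the medians were -2.20 after CBP and -2.67 after P300 knockdown, which argues against library scaling. The 22 members not among the leading genes seen first had medians of -1.77 and -1.90, so the leading genes do not carry the list alone. Lower relative depth than the controls is argued against by the 3 KLF knockdowns, whose depth estimates also lay under the controls. Their list medians were 0.11, 0.16 and 0.0545 after KLF3, KLF4 and double knockdown, against -2.08 and -2.48 after CBP and P300 knockdown. This holds only as far as the estimates do, because the depths are known only up to a simple ratio. No biological explanation was tested, and differences between cultures and effects of these siRNAs other than on their targets stay open.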
